A study of Drosophila melanogaster with 2 samples.

How the data were processed

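Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of both sexes, collected from 0 to 24 h of development, from a transgenic line carrying the homeobox gene bsh (brain-specific homeobox) fused at its C-terminal end to GFP. Per the labels, the immunoprecipitation used an antibody against GFP, chromatin was fragmented by sonication to a size range of 200 to 800 bp, and the 2 samples were separate biological replicates of 1 group. The labels name a possible control experiment, which was not analysed here, and there was no second condition. All comparisons were therefore made among regions, genes and sequence windows, or between the 2 replicates.

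The deposited files were lists of regions on the genome builds dm6 and dm3. Per the file records that accompany them, the authors called a relaxed list, which also holds background regions, for each replicate and for the pooled reads of both, and derived from these a list thresholded by the irreproducible discovery rate (IDR), a measure of how well ranks agree between replicates. Each relaxed list held 30000 regions. A further input file is recorded for each relaxed list and is not described there. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited signal value of each region, as written by the authors' peak caller, was used to describe, rank and filter regions within a list, to compare promoter with other summits within a list, and to correlate matched regions across the replicate lists. Its scale is not given in the sources used here, so levels were not compared between lists. The deposited q-value was on the −log10 scale and reached the same highest value in many regions of each list (7005 of the 30000 pooled dm6 regions), so regions were ranked by signal. The p-value column of the deposited lists was filled with a placeholder and was not used. A further deposited column gave the offset of the summit from the start of the region. The lists hold no read numbers, so the depth of each sample is unknown. The IDR list on dm6 was found to be the 4447 regions of highest signal in the pooled list. The same number of strongest regions was therefore taken from each replicate when replicates were compared. Replicate 2 had 13 mitochondrial regions among these, which left 4434 on chromosome arms.

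Coordinates are 1-based and on dm6 unless stated, and none was converted between builds. Genes were the 13945 protein-coding genes on 2L, 2R, 3L, 3R, 4 and X in Ensembl release 115 (BDGP release 6), and sequence came from the RefSeq copy of the same assembly. Nearest genes are the nearest among the genes in the annotation used here. A summit within 500 bp of an annotated protein-coding transcription start site (TSS) was called a promoter summit, and any other was placed, in this order, in a coding exon, 5′ untranslated region (UTR), 3′ UTR, intron or intergenic sequence. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

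Regions of the replicates were matched by an overlap of at least 1 bp, against 1000 random placements of replicate 2's regions within their chromosomes. Correlations of log signal were computed across regions, which are not independent replicates. Locations were compared by two-sided Fisher's exact tests between the IDR list and the same number of lowest-ranked pooled regions. Signal at promoter and other summits was compared by a two-sided permutation test with 100000 resamples. Regions per chromosome arm were set against assembled length with exact binomial 95% intervals, and other shares have Wilson 95% intervals. Both cover counting error only. For 9 words of 6 bases fixed beforehand, presence on either strand within 100 bp of the summit was compared with a window of the same width centred 600 bp to the right by a two-sided exact McNemar test, with Benjamini-Hochberg adjustment over the 9 words. All 6-base words with at least 50 peaks in the flanks were also ranked as a description.

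A gene was called bound when an IDR summit lay in it or within 2 kb of it. For 17 gene lists, 4 of them controls with no expected link to bsh, the bound share was compared with 10000 random lists of the same size whose members were drawn from the 101 genes nearest in length. P-values were two-sided, and their smallest possible value was 0.0002. They were adjusted by Benjamini-Hochberg over the 17 lists. These tests treat genes, and the word and location tests treat peaks, as the units. They do not measure variation between embryo collections, for which only the 2 replicates stand. Symbols were matched to the annotation directly or, for symbols of 3 or more letters, through older symbols. All members were matched in 13 lists, 24 of 25 in the gap and pair-rule list, 23 of 24 in the Notch list, 15 of 17 in the trachea list and 18 of 19 in the dorsoventral list.

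The genes named were chosen by a rule written before the data were examined, as were the tests, lists, words and most alternatives. The rule took the 20 IDR regions of highest signal, each named by the gene with the nearest TSS and its host gene, bsh itself, up to 4 members of highest signal from each list with adjusted p under 0.05, and up to 2 from each control list. Alternatives changed the promoter distance, the background, the windows and flanks, the rule for a bound gene, the matching, the part of the IDR list used, the build and the replicates. Counting 1 member per 10 kb, a flank at 300 bp, ranks of named regions in each replicate and the build comparison on main arms only were added after seeing the data.

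The statistics were tested on simulated data. A promoter share of 40.0% was recovered as 40.0%. The simulated summits lay either inside the promoter distance or far outside it, so this checks the counting only, not the Fisher's exact tests. Of 200 random gene lists of 30 genes, 5% had p under 0.05, and of 40 lists in which 9 genes were made bound, 92.5% did. These lists were drawn gene by gene at random, so they do not give the error rate for families of related or neighbouring genes. A word placed in windows to raise its share by 8.54 percentage points was found 9.44 points higher, and one not placed differed by 0.989 points.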

Results

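ChIP-seq against GFP was used to map the homeodomain transcription factor bsh in embryos of 0 to 24 h carrying a bsh-GFP fusion. No control was analysed here, so it was not tested how much of the signal would also appear without the fusion protein. In the literature bsh is known as a regulator of neuron identity in the developing brain. The data comprised 1 group with 2 biological replicates, and the depth of each is unknown because the region lists hold no read numbers. The IDR-thresholded list held 4447 regions on dm6 with a median width of 440 bp. Its signal values, the authors' own, ran from 119.6 to 2129.83 with a median of 182.7. Overlapping regions merged to 4182. On dm3 the corresponding list held 4646 regions, 4.47% more.

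The first comparison was between the replicates. The 20 regions of highest pooled signal, from those near CG11362 and larp to that in Lk6, ranked 23 or better in replicate 1 and 44 or better in replicate 2; they were chosen on the signal of both. Replicate 2 on its own was led by mitochondrial regions, 13 in all with signal up to 3702.74, of which replicate 1 held 0, and its strongest nuclear region, that near CG11362, had rank 11. Among the 4447 strongest regions of each replicate, 3357 of replicate 1 (75.5%) overlapped one of replicate 2, and 74.4% of replicate 2 overlapped one of replicate 1. Random placement gave 2.46% on average and at most 3.22% (permutation p = 0.000999, the smallest that 1000 placements can give). Signal in the matched regions correlated with Spearman's rho 0.746 and Pearson's r 0.827 across regions. Over all relaxed regions rho was 0.598.

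The strongest regions lay near genes of varied function. The highest signal, 2129.83, belonged to 2R 22569680 to 22570533, in an intron of dnr1 and 7674 bp from the nearest TSS, that of CG11362. Next came larp, which encodes an RNA-binding protein (3R 28326260 to 28326886, promoter, signal 1701.96), an intron of CG32772 (X 4909971 to 4910920, signal 1690.12) and the promoter of Ugalt, a UDP-galactose transporter gene (X 2703678 to 2704070, signal 1623.94). An intergenic region 7655 bp from RYBP had a signal of 1600.56, and an intron of CG11050 had 1599.81. The promoters of Cat, which encodes catalase, and PNPase, which encodes polynucleotide phosphorylase, had 1514.22 and 1470.2. The zinc finger gene cbt was nearest to 2 of the 20 regions. One, with signal 1417.42, lay in an intron of its neighbour ush 1369 bp from the cbt TSS, and the other, with 1164.94, in a 5′ UTR.

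The summit at puc, which encodes a phosphatase of the JNK pathway, was 1 bp from its TSS (3R 8105837 to 8106800, signal 1206.44). A region 6070 bp from scyl, a negative regulator of TOR signalling, had a signal of 1380.12, and an intron of the kinase gene Lk6 had 1141.79. The others were nearest to CG4004 (1400.21), CG13323 (1369.38), CG8788 (1306.48), CG14100 (1283.88), speck (1214.19), HmgZ (1171.05, in a region also covered by HmgD) and yip2 (1157.04). Of the 20 summits, 8 were at promoters, 7 in introns, 4 intergenic and 1 in a 5′ UTR.

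Around bsh (2L 19765776 to 19769067, minus strand), the IDR regions lay downstream of the gene, and each was nearest to the TSS of another gene. Summits at 19764332 and 19764531 were 1444 and 1245 bp beyond its 3′ end and nearest to the TSS of fbp, with signal 211.7 and 183.4. These 2 regions overlapped and matched the same replicate 2 region, of rank 2782. A stronger summit at 19758682, signal 292.9, lay 7094 bp beyond bsh and was nearest to CG10628. The region closest to the bsh TSS, at 311 bp, had a signal of 98.1 and rank 6106 in the pooled list, outside the IDR list. It ranked 6122 in replicate 1 and 8476 in replicate 2.

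**Figure D1:**
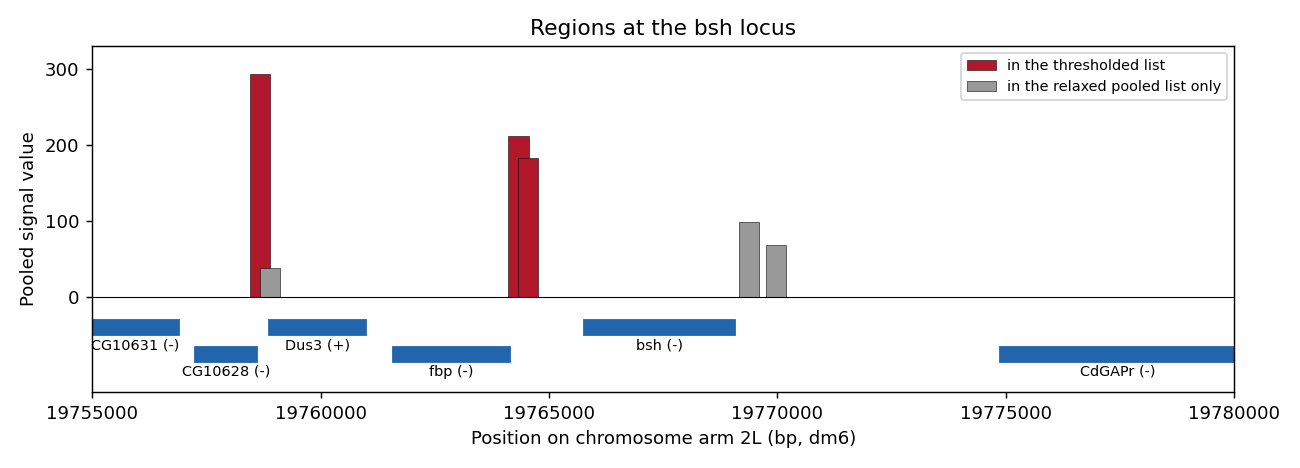
Regions of the pooled list (height, authors' signal value) by position on chromosome arm 2L in bp (dm6), with protein-coding genes and their strands beneath. Red regions, in the IDR list, lie downstream of bsh, nearest to the TSSs of fbp and CG10628, with signal 183.4 to 292.9. The grey region next to the bsh TSS reaches 98.1.

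The location of summits was compared between the IDR list and the lowest-ranked pooled regions, which could have passed the threshold and did not. Promoters held 36.9% of IDR summits (1642 of 4447, 95% interval 35.5 to 38.4%) and 18.5% of lowest-ranked summits (odds ratio 2.59, Fisher's exact p = 2.62e-85). Coding exons held 0.157% against 5.13% (exact p = 1.62e-59) and 3′ UTRs 0.742% against 4.83% (exact p = 9.97e-35). Introns held 43.0% against 47.6% and intergenic sequence 18.5% against 23.3%, while 5′ UTRs were at 0.652% and 0.72% (exact p = 0.797). In the replicates' own strongest regions the promoter share was 37.7% ± 2.53 (SD, n = 2), with 35.9% in replicate 1 and 39.5% in replicate 2. The lowest-ranked regions came from the pooled list alone, so this SD does not measure the spread of the difference. The regions next in rank below the IDR list did not differ from it in promoter share (37.1%, odds ratio 0.991, exact p = 0.861). By rank in the pooled list the share was 36.5% for ranks 1 to 3000, 36.7% for ranks 6001 to 9000 and 18.1% for the last 3000. It was higher at the very top: 46.4% of the top 500 regions (95% interval 42.1 to 50.8%) and 50% of the top 100 (40.4 to 59.6%).

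**Figure D2:**
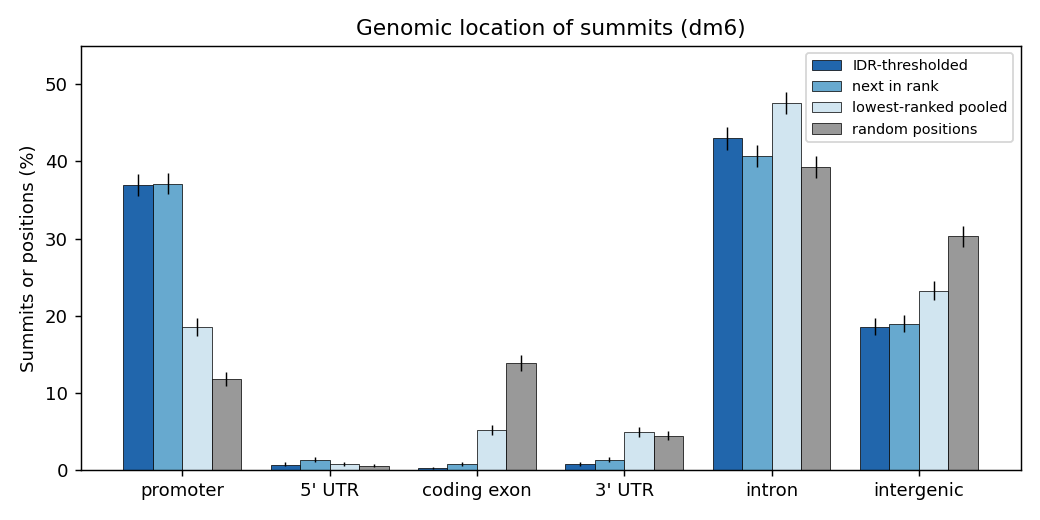
Share of summits or positions (%) in each location for the IDR list, the 4447 regions next in rank, the 4447 lowest-ranked pooled regions and 4447 random positions, with Wilson 95% intervals. Promoters hold 36.9% of IDR summits and 11.7% of random positions, and coding exons 0.157% and 13.9%.

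Signal at promoter and other summits was compared within the IDR list. Promoter summits had a median of 181.5 and the others 183.0, a log2 difference of -0.01 that the test did not separate from 0 (permutation p = 0.583). Among the stronger 2223 regions the promoter median was higher, 289.7 against 265.9 (permutation p = 0.0001), and with promoters limited to 200 bp it was lower, 173.2 against 184.9 (permutation p = 0.00085).

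Regions per chromosome arm were compared with assembled length. Arm 3L held 1025 regions, 1.13 times its share by length (95% interval 1.07 to 1.19), and X held 835, or 1.10 times (1.03 to 1.17). Chromosome 4, small and largely heterochromatic, held 15 regions, 0.344 times its share (0.193 to 0.567). The intervals of 2L (1.01), 2R (0.994) and 3R (0.953) included 1. No region lay on Y, which allows a share of up to 0.0675%. Set against gene number instead of length, 2L (0.911, interval 0.854 to 0.972), 2R (0.895, 0.84 to 0.953) and 3R (0.907, 0.858 to 0.958) were below 1, chromosome 4 was at 0.589, 3L at 1.18 and X at 1.19.

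The sequence at summits was compared with a flank of the same peak, 600 bp to the right. TAATTA, the core recognition word of the homeodomain class to which bsh belongs, was in 13.6% of summit windows and 12.6% of flanks, a ratio of 1.08 that did not pass (exact McNemar p = 0.161, adjusted 0.207). Bases G and C made up 38.4% at summits and 41.7% at flanks, and no word ratio was corrected for this. GAGAGA, the word of the GAGA factor, was in 16.3% of summit windows and 8.93% of flanks (ratio 1.83, adjusted exact p = 2.16e-24). Its ratio was 1.77 in replicate 1 and 2.04 in replicate 2. Lower at summits were CAATTA (15.9% against 18.7%, adjusted exact p = 0.00181), TAATCC (5.64% against 7.13%, adjusted exact p = 0.0109) and ATCGAT (4.45% against 6.77%, adjusted exact p = 1.02e-05). CAATTA and TAATCC were no longer past the threshold with windows of 50 bp each side (unadjusted exact p = 0.112 and 0.05002) or in the stronger 2223 regions (0.054 and 0.136), nor was CAATTA at promoter summits (0.326). CAGGTA, CAGCTG, TGTTTA and AGATAA had ratios of 0.883, 0.881, 1.08 and 1.08 and did not pass against the right flank in the main setting. Against the left flank CAGGTA (ratio 0.694, adjusted exact p = 0.000765) and CAGCTG (ratio 0.825, adjusted exact p = 0.0113) passed as lower at summits. Both were also lower against both flanks at 1000 bp (ratios 0.837 and 0.859, unadjusted exact p = 0.0189 and 0.00259). CAGGTA was lower at promoter summits (0.663, unadjusted exact p = 0.0156). CAGCTG was lower with windows of 50 bp each side (0.72, unadjusted exact p = 0.00333) and at distal summits (0.775, 0.0081). With windows of 200 bp each side CAGCTG was higher (ratio 1.13, unadjusted exact p = 0.0107). With both flanks at 1000 bp TGTTTA had a ratio of 1.13 (unadjusted exact p = 8.14e-05), and with windows of 50 bp each side AGATAA had 1.21 (unadjusted exact p = 0.022). TGTTTA was also past 0.05 in the stronger 2223 regions (1.16, unadjusted exact p = 0.0109), replicate 1 (1.11, 0.0187) and replicate 2 (1.11, 0.0182). AGATAA was so in replicate 1 (1.13, unadjusted exact p = 0.0323). Neither word was past 0.05 under the other alternatives. For TAATTA, too, the call and direction depended on the windows and regions used: the ratio was 1.23 in the stronger 2223 regions (exact p = 0.00696) and 0.884 with windows of 200 bp each side (exact p = 0.00198). A flank 300 bp away, chosen after seeing the data, gave 1.37 (exact p = 7.62e-08). In the ranking of 2077 words by summit-to-flank ratio, TAATTA was in place 613, and ACACTG, AGTGTA and GTGCAC led with ratios of 2, 1.99 and 1.93.

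**Figure D3:**
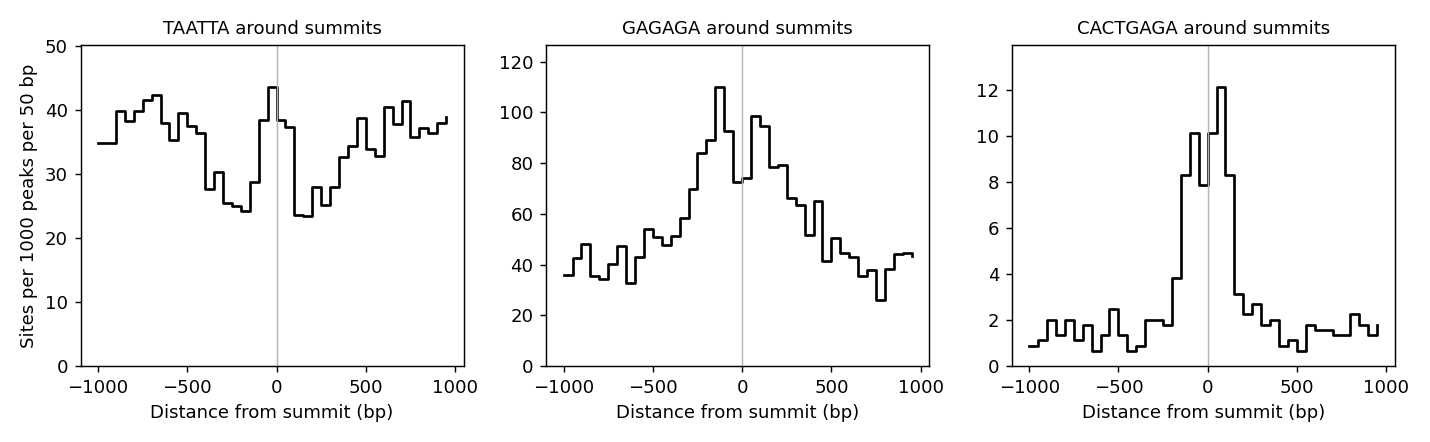
Sites of TAATTA, GAGAGA and CACTGAGA per 1000 peaks in bins of 50 bp, by distance from the summit in bp. TAATTA averages 41.0 within 50 bp, 26.96 from 150 to 400 bp and 37.8 from 500 to 1000 bp, while GAGAGA averages 99.1 from 50 to 150 bp and 41.1 from 500 to 1000 bp.

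Bound genes were compared with genes of the same length for each of the 17 lists. Of 13945 genes, 3470 (24.9%) were bound. Bound more often than matched genes were ribosomal protein genes, Notch pathway genes and mitochondrial ribosomal protein genes. Bound less often were the Dpr and DIP genes, which encode interacting neuronal cell surface proteins, pan-neuronal and synaptic genes, homeobox genes, and odorant and gustatory receptor genes.

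Of the Notch pathway genes, 14 of 23 were bound (60.9%, against 30.7% of matched genes, adjusted permutation p = 0.0051), and the share was 56.5% in replicate 1 and 60.9% in replicate 2. The strongest members were neur, a ubiquitin ligase gene (signal 788.85, intron), mam, a coactivator gene with 12 summits in or near it (highest signal 599.0), fng, a glycosyltransferase gene (515.5), and the E(spl) complex gene E(spl)mdelta-HLH (509.7), whose summit was nearest to CG43116. The strongest mam summit, in an intron of mam, was nearest to the TSS of CG18371. The Notch call was lost when only summits in the gene body (adjusted permutation p = 0.343), within 1 kb of a TSS (0.0516) or with the gene's TSS nearest (0.185) were counted.

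Of the ribosomal protein genes, a control list, 49 of 85 were bound (57.6%, against 17.0%, adjusted permutation p = 0.00113). The share was 57.6% in replicate 1 and 61.2% in replicate 2. The strongest were RpS19b (705.7) and RpL31 (410.8), though these summits were nearest to the TSSs of CG5854 and CG1827. Mitochondrial ribosomal protein genes were bound in 20 of 73 cases (27.4%, against 14.4%, adjusted permutation p = 0.013), led by mRpS23 (1092.82, nearest to CenG1A) and mRpL23 (601.2). Most of these 20 had summits only outside the gene: with the gene body alone 2 of 73 were bound, as with nearest-TSS assignment. For these genes the direction turned when only the gene of the nearest TSS was counted (6.03 percentage points lower than matched genes, adjusted permutation p = 0.185). The call was lost under 4 further alternatives, the gene body alone among them.

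Of the Dpr and DIP genes, 4 of 31 were bound (12.9%, against 49.6%, adjusted permutation p = 0.00113): DIP-alpha (370.5), DIP-gamma (181.9), dpr14 (171.7) and dpr20 (126.6). The summits of DIP-alpha, DIP-gamma and dpr14 were nearest to the TSSs of ppk8, CG11828 and spidey. The bound share of the list was 9.68% in each replicate. Of the pan-neuronal and synaptic genes, 4 of 22 were bound (18.2%, against 51.1%, adjusted permutation p = 0.0109): the RNA-binding protein genes elav (567.5) and Rbp9 (280.9), Syn, which encodes synapsin (263.1), and Syx1A, which encodes a syntaxin (159.2). The Syn summit was nearest to the TSS of Timp. Without length matching neither the Dpr and DIP list nor the pan-neuronal list differed from other genes (adjusted permutation p = 0.258 and 0.79). With matching on the sum of gene length and intergenic space instead, which does not hold length itself equal, the pan-neuronal call was lost (adjusted permutation p = 0.451). It was also lost under 3 other alternatives.

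Of the homeobox genes other than bsh, 26 of 96 were bound (27.1%, against 39.8%, adjusted permutation p = 0.0248), with the highest signal at NK7.1 (685.6), ct (418.4), zfh1 (336.5) and tup (333.9, nearest to CG10602). Without length matching this list was 2.21 points above other genes (adjusted permutation p = 0.79), and the call was lost under 3 other alternatives. Of the odorant and gustatory receptor genes, 5 of 119 were bound (4.2%, against 18.6%, adjusted permutation p = 0.00113), among them Gr89a (268.7) and Gr32a (225.1). Their summits were nearest to the TSSs of Cad89D and Idua. The call for receptor genes was lost with nearest-TSS assignment (adjusted permutation p = 0.106).

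The other 10 lists did not pass. The dorsoventral and BMP/EGF signalling list had 12 of 18 genes bound (66.7%, against 41.7%, adjusted permutation p = 0.0952) and passed under 5 of 10 alternatives. Axon guidance and adhesion genes were bound in 18 of 30 cases (60%), and passed as bound more often with matching on gene length plus intergenic space (adjusted permutation p = 0.0278) and without matching (0.00085). Mesoderm and muscle genes were bound in 14 of 31 cases, lamina and optic lobe identity genes in 7 of 16, and neuroblast and temporal patterning genes in 7 of 25. Gap, pair-rule and segment polarity genes were bound in 7 of 24 cases, glial genes in 6 of 12, gut genes in 6 of 14, and trachea and epidermis genes in 8 of 15. Cuticle protein genes, a control list, were bound in 7 of 70 cases (adjusted permutation p = 0.173), the strongest being Cpr31A (529.5, nearest to Pen) and Cpr72Ea (398.8). Cuticle protein genes passed as bound less often with matching on gene length plus intergenic space (adjusted permutation p = 0.0184) and without matching (0.00907).

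**Figure D4:**
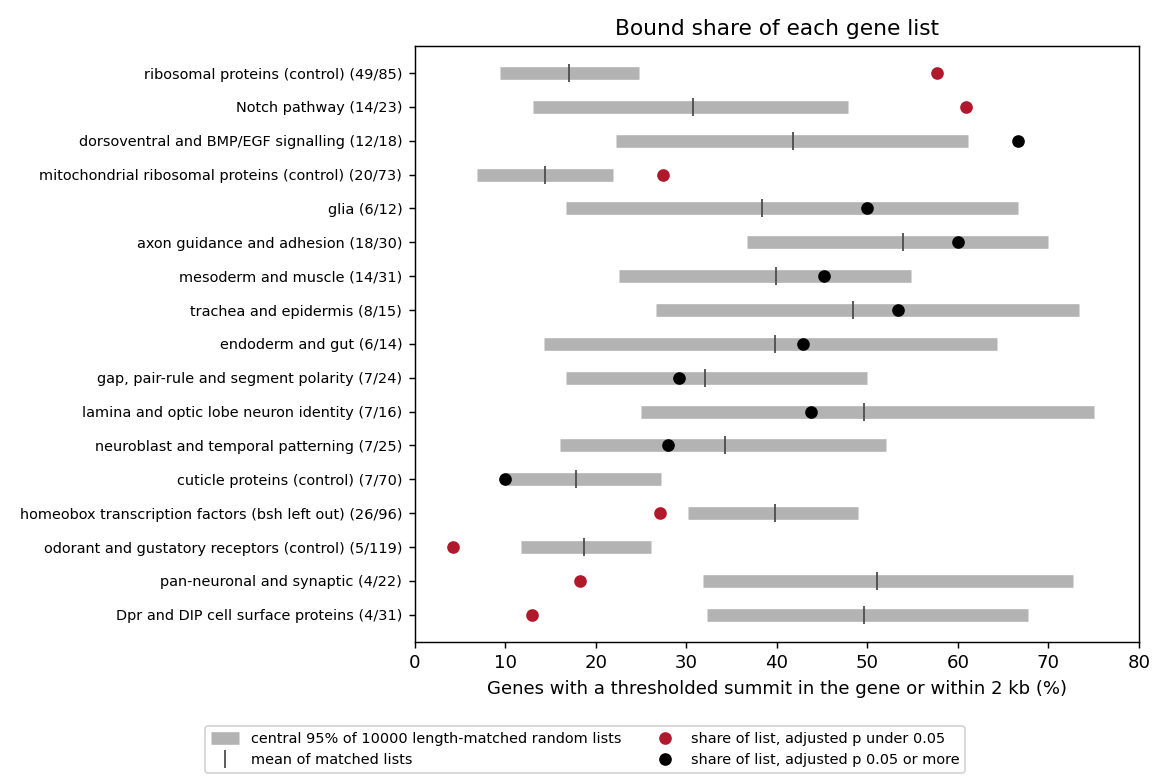
Share of each list's genes with an IDR summit in the gene or within 2 kb (points, %; red, adjusted permutation p under 0.05), with the mean (tick) and central 95% (grey bar) of 10000 length-matched random lists. Ribosomal protein genes lie at 57.6% against 17.0%, and Dpr and DIP genes at 12.9% against 49.6%.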

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

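Only 1 result stood apart as a signal outside the main measurement. On dm6, replicate 2 held 13 regions on the mitochondrial chromosome, with a highest signal of 3702.74 against 980.1 at the strongest nuclear region, while replicate 1 and the pooled list held 0. On dm3 replicate 2 held 4 such regions, of which the strongest had rank 172. No explanation of these regions was tested.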

How the results depend on the processing

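Of 363 alternative values, those that changed a main result or turned a direction are given here, and among single words and lists a further 22 gained and 22 lost a call in the same direction; their cause was not tested, except that a smaller part of the list holds fewer regions by construction. The flank at 300 bp and the count of 1 member per 10 kb were added after seeing the data. Unknown depth limits every comparison of signal between lists. No paired analysis was possible because there was 1 group.

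The stronger part of the IDR list held 2223 regions. Replicate overlap was 63.6% with 50% of each region required, 66.2% with summits within 100 bp, 80.4% for the top 500 and 80.2% for the top 1000. Spearman's rho was 0.797 with summits within 100 bp and 0.598 over all relaxed regions. The promoter odds ratio was 0.991 against next-ranked regions. The log2 difference in signal between promoter and other summits was -0.0943 at 200 bp, 0.0254 at 1000 bp and 0.124 in the stronger part, and -0.00823 to 0.0379 when either replicate was left out.

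The TAATTA ratio was 0.884 with windows of 200 bp each side, 0.968 at promoters, 1.23 in the stronger part and 1.37 with the flank at 300 bp, and 0.958 to 1.07 when either replicate was left out. Among the other words, CAGGTA turned to 1.09 at distal summits, CAGCTG to 1.13 with windows of 200 bp (unadjusted exact p = 0.0107) and 1.05 at promoters, and AGATAA to 0.949 with windows of 200 bp. GAGAGA and ATCGAT kept their calls under each alternative run.

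Lists bound less often numbered 4, but 1 with nearest-TSS assignment, the Dpr and DIP list, and 2 without matching. Those 2 were the odorant and gustatory receptor list and the cuticle protein list, and the latter was not among the 4. All ribosomal protein alternatives kept the call. Differences from matched genes that changed sign, in percentage points, were as follows. In the gene body only they were 1.12 for neuroblast, 9.64 for gap and pair-rule, -3.47 for mesoderm, -0.517 for gut and -5.21 for trachea genes. Within 5 kb they were 0.944 for lamina and -0.807 for trachea genes. With nearest-TSS assignment they were 1.72 for lamina, 13.97 for gap and pair-rule and -6.03 for mitochondrial ribosomal protein genes. In the stronger part they were -6.03 for axon guidance, 0.932 for gap and pair-rule and -13.3 for gut genes. With matching on gene length plus intergenic space, lamina genes were at 10.5. Without matching they were 2.21 for homeobox, 18.9 for lamina, 2.98 for neuroblast and 4.19 for gap and pair-rule genes. When either replicate was left out, mesoderm genes were at -2.67 to 5.68 and gut genes at -11.1 to -0.196.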

Other observations

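The gene families in this part were chosen after the main results were seen. The test of the longer word on other chromosome arms, its correction for all words, both tests of neuronal genes in general and the local word ratio were chosen only after the result they measure was seen. Of 8 further families, 2 passed, both with few bound genes. Cytochrome P450 genes, which encode oxidative enzymes, were bound in 5 of 85 cases (5.88%, against 22.7% of length-matched genes, adjusted permutation p = 0.0008), and ionotropic receptor genes, which encode chemosensory channels, in 2 of 60 (3.33%, against 22.8%, adjusted permutation p = 0.0008). With nearest-TSS assignment the P450 call was lost (adjusted permutation p = 0.677), and that of the ionotropic receptors was kept (0.0336). Odorant-binding protein genes were bound in 6 of 51 cases and Jonah protease genes in 0 of 16, and neither family passed.

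Ribosomal protein genes were bound far more often than genes of their length, although they were chosen as a control. Counting the peaks of neighbours for short genes in dense regions is argued against: with nearest-TSS assignment the excess was 46.8 percentage points, above the central 95% of matched lists. A preference for constitutively expressed genes in general stays open, because 1 of 3 further families, translation factors (19 of 51, adjusted permutation p = 0.088), lay above the matched range, while proteasome (8 of 48) and complex I genes (10 of 40) did not, and the translation factors were not above it with 1 gene per 10 kb (36%, adjusted permutation p = 0.193) and did not pass with nearest-TSS assignment (0.538). Signal that would also appear without the fusion protein was not tested, since no control was analysed here. No biological explanation was tested.

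Neuronal effector genes, the Dpr and DIP list with the pan-neuronal list, were bound less often than genes of their length. Poor matching of very long genes was tested on the lists together. With only summits within 1 kb of a TSS counted the shortage stayed: 5 of 53 were bound, -22.2 points from matched genes (permutation p = 0.0004). The pan-neuronal list alone did not pass (adjusted permutation p = 0.139). The matched genes were again chosen by length, so this test cannot exclude poor matching. A shortage at neuronal genes in general cannot be told apart on the first test chosen, since axon guidance genes lay 6.08 points above their matched mean and neuroblast genes -6.29 points from theirs, both inside the matched range. A later test, chosen with the counts known, set the lists against each other: the odds ratio of Dpr and DIP against axon guidance genes was 0.0988 (Fisher's exact p = 0.000162), and that of the pan-neuronal list 0.148 (exact p = 0.00414). Without length matching the differences were -12.0 points for Dpr and DIP genes and -6.71 for the pan-neuronal list, and neither list passed. Matching on gene length plus intergenic space instead does not hold length itself equal. With it Dpr and DIP genes still passed (-20.7 points, adjusted permutation p = 0.0403) and the pan-neuronal list did not (-11.9 points). Both shortages were thus smaller when the matching was changed. No biological explanation was tested.

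A longer word stood out at summits more than TAATTA did: CACTGAGA, chosen by score on 2L, 3L and X, was 6.25 times as frequent at summits as at flanks on the other arms (4.13% against 0.661%, exact McNemar p = 2.71e-12), although words ranked over all arms had been seen by then, so these arms are not independent support. Choice of the best of many words by chance is argued against by the exact McNemar p over all arms. Multiplied by the 32896 possible words of 8 bases, this p was 5.67e-22. Of 165 windows with the word, 0 shared 30 bases with another, which argues against near-identical copies of one repeat only. Diverged or shorter repeat copies stay open, because this test cannot detect them. An extended form of the longer word, which also contains the GAGA factor word, was in 72 summit windows and 4 flanks over all arms (ratio 18). For TAATTA, the test of AT-rich sequence came out as neither outcome foreseen: its ratio of 1.05 over both flanks was at percentile 0 of the 35 other words of A and T (median 1.29), below them all rather than within or above. A local rise beyond such words is not seen either, since its ratio of 1.55 within 50 bp against 150 to 400 bp was at percentile 11.4. The protein that binds the longer word was not tested.

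A hypothesis that stress-response genes are near the strongest summits was followed up on heat shock genes, leaving out Hsp27, which had been seen among the strongest. Any IDR summit counted, whatever its rank, so the test does not measure nearness to the strongest. Heat shock genes were bound in 8 of 18 cases, 24.0 points above matched genes. The adjusted permutation p over 8 families was 0.088, and with 1 gene per 10 kb the share of 36.4% lay inside the matched range. The hypothesis stays open.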
